A study of Mus musculus with 15 samples.

How the data were processed

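The series holds RNA sequencing of mouse embryonic stem cells of the ES-R1 line, kept in serum-free medium with N2 and B27 supplements, per the labels. The cells carried a control siRNA or an siRNA against Vprbp and were sampled in 4 days of differentiation. Cells received no addition, Activin A at 25 ng/ml or the inhibitor SB. The sample titles write the inhibitor as SB431524 and the series text as SB431542, its dose is not given in the sources used here, and it is called SB throughout. There were 5 groups of 3 libraries. SB was combined with the control siRNA only. Groups and replicate numbers were taken from the sample titles, and each column of the table was matched to its sample through the number in the sample's description.

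The deposited table holds fragment counts per gene symbol for 15 libraries, without normalization. HTSeq 0.6.1p1 and the mouse build mm10 are named in the submitters' processing notes. The aligner, the annotation and the strand setting are not given in the sources used here, so overlapping or antisense genes cannot be told apart, and reads of near-identical copies may be split. The table has 24456 rows, of which 5 are HTSeq tallies and were kept out of library sizes and tests. Per library, 10.3% to 16.0% of all fragments fell outside genes, 0.678% to 0.722% were ambiguous and 27.7% to 29.5% were not aligned. The tally of non-unique alignments was 0 in every library. The counts assigned to genes made up 55.6% to 60.4% of fragments, between 11.1 M and 15.5 M (M, mega) per library. At these depths a count of 0 allows up to 0.193 to 0.269 CPM, taking 3 counts as the limit. Such limits cover counting error only.

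Genes were kept when edgeR's filterByExpr passed them (minimum count 10), which left 14600 of 24451 genes. Counts were scaled by TMM factors, which lay between 0.985 and 1.02. The tests were edgeR 4.0.16 quasi-likelihood tests (robust glmQLFit and glmQLFTest) in R 4.3.3, fitted to all 15 libraries with 1 mean per group, with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. Expression values are CPM on the scaled library sizes, as mean ± SD with n = 3 per group, and log2 fold changes carry the standard error of the fit. A gene is said to have risen or fallen only where it passed this threshold. The biological coefficient of variation was 8.76%. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. Every pair of replicates differed by more than sampling noise, with a chi-square per degree of freedom of 2.82 to 16.7 over genes.

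Before the data were examined, 7 comparisons, the alternatives, the rule for named genes and 28 lists of textbook marker and pathway genes were fixed. Lists were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, and again with the correlation estimated from the data. The test fry, fixed beside camera, asks whether a list moves by itself rather than against all other genes. Adjustment was over the 28 lists of a comparison. Each list is also given as the number of members called over all genes tested and the number called with p-values adjusted over the list alone. The rule named the 5 largest rises and 5 largest falls per comparison among genes past the threshold with a mean log2 CPM of at least 1 and group ranges that did not overlap (not required for the difference of responses), leaving out unnamed gene models. It also named up to 4 members with the smallest p-values of each list described, and always Vprbp, Lefty1, Lefty2 and Nodal. Averages of the knockdown effect and of the Activin effect over the other factor were added after seeing the data.

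The alternatives were RLE size factors or library totals, no filter or a filter of 1 CPM in at least 3 libraries, DESeq2 1.42.0, a replicate block, a fit of only the libraries compared, a test against a fold of 1.5, and leaving out each library. Correlations between comparisons that share control libraries were set beside counts simulated 20 times with no effect. The procedure was tested on simulated counts for the knockdown comparison without Activin over 14435 genes. It recovered 36% of genes changed by 1.3-fold, 62% at 1.5-fold, 70% at 2-fold and 88% at 4-fold, with 12 false calls among 140. This was a single draw with each gene independent and no shifts of a whole library, so recovery in the real libraries may differ.

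Replicate numbers were checked as a possible pairing, from the data alone. Deviations of same-numbered libraries from their group means correlated over genes at 0.12, 0.20 and 0.37 between the untreated control siRNA and Vprbp siRNA groups. No other pair of groups passed 0.1 at all 3 numbers, so a block is given beside the knockdown comparison without Activin. Positions come from a RefSeq gene table on GRCm38, the assembly also called mm10, in which 23249 of 24451 symbols matched directly and 1091 through a synonym.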

Results

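The transcriptome of mouse ES-R1 embryonic stem cells was profiled in 4 days of differentiation under manipulation of Activin/Nodal signalling. Activin A signals through the type I receptor ALK4, which phosphorylates Smad2 and Smad3. SB inhibits ALK4 and the related receptors ALK5 and ALK7. Vprbp, also named Dcaf1, is a substrate receptor of the CRL4 ubiquitin ligase. There were 5 groups of 3 libraries: control siRNA and Vprbp siRNA without addition, both siRNAs with Activin A at 25 ng/ml, and control siRNA with SB. Libraries held 11.1 M to 15.5 M counts assigned to genes (M, mega).

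Principal component 1 held 48.7% of the variance and ran from the Activin groups to the SB group. Principal component 2 held 12.1%. Of the untreated libraries, replicate 3 of control siRNA and replicate 3 of Vprbp siRNA lay farthest toward the SB group, at 15.6 and 7.27 on component 1. Replicate 1 of Vprbp siRNA with Activin lay apart on component 2, at -35.0.

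**Figure D1:**
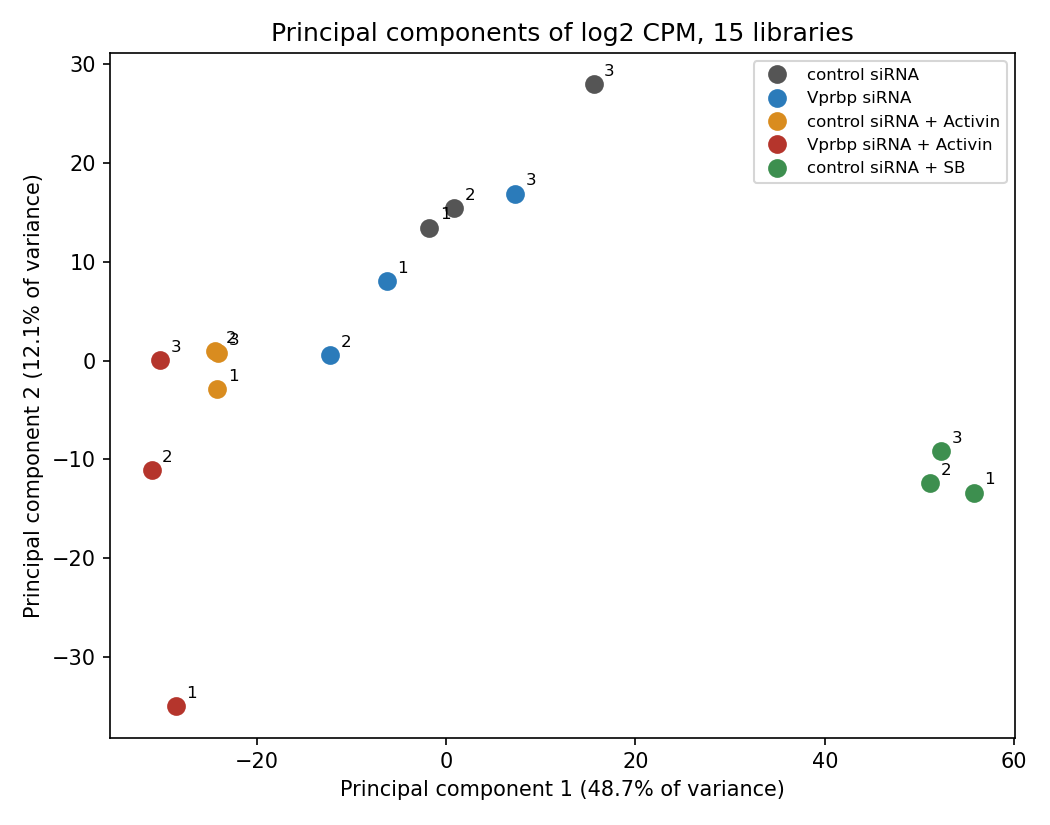
Principal components 1 (x axis) and 2 (y axis) of log2 CPM, in component units, with 1 point per library, coloured by group and numbered by replicate. The SB libraries lie between 51.1 and 55.8 on component 1, and the control siRNA libraries with Activin between -24.4 and -24.1.

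The knockdown itself was partial in RNA at sampling. Vprbp protein was not measured here, and whether the knockdown was deeper earlier in the 4 days is not known. Vprbp (chromosome 9, 106814169 to 106880992, GRCm38) was at 171.0 ± 3.6 CPM (SD, n = 3) with control siRNA and 122.2 ± 8.9 CPM with Vprbp siRNA, a decrease of 28.6%. With Activin it was at 179.1 ± 4.4 and 138.3 ± 9.2 CPM, a decrease of 22.8%. Every Vprbp siRNA library lay below every control siRNA library at the same Activin level, and an exact two-sided permutation test gave p = 0.1 in both cases, the smallest that 3 against 3 allows. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the log2 fold changes were -0.49 ± 0.06 (adjusted p = 0.0020) and -0.37 ± 0.06 (adjusted p = 0.037). The series has no further Vprbp siRNA group and no rescue group. Knockdown effects below are therefore those of the siRNA contrast, in which loss of Vprbp cannot be told apart from other effects of the siRNA.

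**Figure D2:**
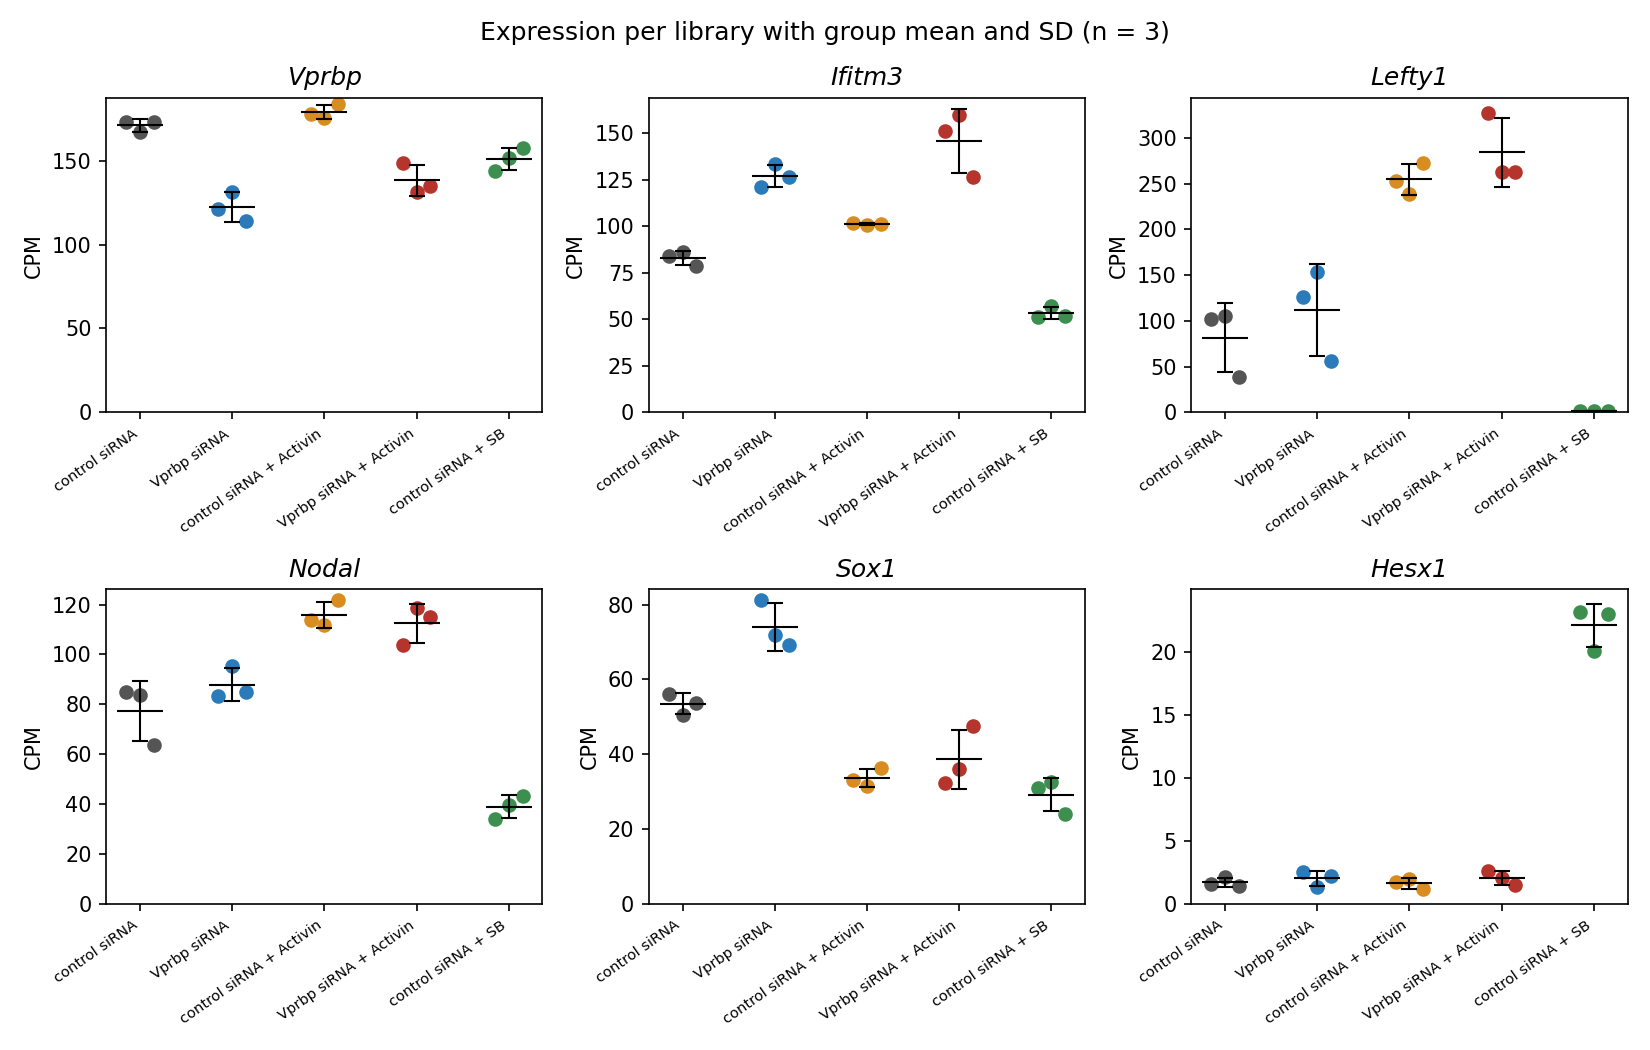
CPM of 6 genes (y axes, starting at 0) in the 5 groups (x axes). Points are libraries and bars the group mean and SD (n = 3). Vprbp is lower in both Vprbp siRNA groups, Ifitm3 higher, Lefty1 falls from 81.8 to 1.6 CPM with SB, and Hesx1 is near 2 CPM outside the SB group.

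Activin in control siRNA cells raised most feedback genes of its own pathway. The Nodal antagonists Lefty1 (chromosome 1, 180935022 to 180938401) and Lefty2 (chromosome 1, 180893108 to 180899107) rose from 81.8 ± 37.9 to 254.7 ± 16.7 CPM and from 42.8 ± 22.7 to 197.5 ± 16.95 CPM. These neighbouring paralogs may share reads. The ligand gene Nodal (chromosome 10, 61417972 to 61425338) rose from 77.4 ± 12.0 to 115.8 ± 5.3 CPM. The log2 fold changes were 1.64 ± 0.39, 2.20 ± 0.42 and 0.58 ± 0.10. Of 12 feedback genes 8 rose and 0 fell, and 9 rose with p-values adjusted over the list alone. Pmepa1 (0.75 ± 0.09) and Smad7 (1.05 ± 0.17), inhibitors of receptor signalling, were among them. This list was called by camera (adjusted p = 1.7e-16), and adjusted p = 0.029 with an estimated correlation.

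In all, 705 of 14600 genes were called, 431 higher and 274 lower. The largest rises were those of Trim67 (2.75 ± 0.51), the lysophosphatidic acid producing enzyme Enpp2 (2.52 ± 0.57), the interferon-inducible GTPase Irgm2 (2.29 ± 0.40), Lefty2 and Pga5 (2.19 ± 0.43). The largest falls were those of the growth factor gene Ptn (-2.87 ± 0.57), the retinoic acid induced gene Stra8 (-1.92 ± 0.14), the collagen gene Col3a1 (-1.76 ± 0.42), the homeobox gene Meis1 (-1.71 ± 0.18) and Insm1 (-1.58 ± 0.29). Stra8 was the most abundant of these, falling from 249.4 ± 25.9 to 66.1 ± 6.5 CPM.

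Some markers of the neural plate fell and some epithelial genes rose. In the neuroectoderm list 4 of 23 genes fell, among them Pax6 (-1.03 ± 0.14), Sox1 (-0.67 ± 0.12) and the neuronal tubulin Tubb3 (-0.61 ± 0.12), and 2 rose, among them Fgf15 (1.74 ± 0.22). With adjustment over the list alone 8 fell and 3 rose. The list was called lower by camera (adjusted p = 0.0055), but adjusted p = 0.19 with an estimated correlation, and it was not called without control siRNA with Activin replicate 2 (adjusted p = 0.057) or without the 3 libraries that lay apart (adjusted p = 0.098). The epithelial genes Epcam (0.56 ± 0.08), Grhl2 (0.63 ± 0.12) and Cdh1 (0.29 ± 0.07) rose. They belong to a list of epithelial and mesenchymal genes of which 4 of 16 rose and 1 fell, or 6 and 3 adjusted over the list alone, and which was not called (camera adjusted p = 0.095).

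Of 15 genes of the primed epiblast, the de novo DNA methyltransferase Dnmt3b (0.90 ± 0.12) and Foxd3 (1.67 ± 0.27) rose, and 8 rose with adjustment over the list alone. Fgf5 was at 10.4 ± 6.3 CPM without and 35.1 ± 1.7 CPM with Activin and did not pass (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.062). The list was called higher (camera adjusted p = 1.4e-07), but adjusted p = 0.22 with an estimated correlation. Of 13 primitive streak genes 2 rose, among them Fgf8 (1.86 ± 0.47), or 3 adjusted over the list alone, while T (brachyury) was at 2.4 ± 0.3 and 13.0 ± 3.1 CPM and did not pass (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.072). Camera called the list higher (adjusted p = 0.00021), with adjusted p = 0.36 with an estimated correlation. Of 15 interferon response genes 3 rose, among them Bst2 (0.48 ± 0.12) and the RNA sensor Ddx58 (0.64 ± 0.16), or 6 adjusted over the list alone. That list was called higher (camera adjusted p = 0.00021), but adjusted p = 0.13 with an estimated correlation.

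Of 19 naive pluripotency genes Zfp42 (-0.36 ± 0.08) and Spp1 (-1.06 ± 0.24) fell, or 4 adjusted over the list alone. That list was called lower (camera adjusted p = 0.0079), but adjusted p = 0.42 with an estimated correlation. Of 12 Hox genes 1 fell, or 3 adjusted over the list alone. Camera called the Hox list lower (adjusted p = 0.0055), with adjusted p = 0.23 with an estimated correlation. Among markers of other cell types, 1 of 12 fibroblast genes, Col3a1, fell, or 4 adjusted over the list alone, and the list was called lower (camera adjusted p = 0.036), but adjusted p = 0.42 with an estimated correlation. Extraembryonic endoderm genes moved both ways, with Dab2 (1.01 ± 0.11) among 4 of 20 that rose and Lama1 (-0.86 ± 0.14) and Plat (-1.28 ± 0.21) among 3 that fell, or 4 and 6 adjusted over the list alone, and the list was not called (camera adjusted p = 0.64). Leaving out 1 library moved the total between 265 calls without control siRNA with Activin replicate 3 and 721 without control siRNA replicate 1. Lefty1 and Enpp2 lost their calls in every one of these 6 fits, and Lefty2, Pga5, Trim67, Ptn, Col3a1, Fgf8, Bst2, Ddx58, Zfp42, Spp1 and Cdh1 in at least 1.

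SB moved control siRNA cells further from the untreated state than Activin did, with 3294 genes called, 1642 higher and 1652 lower. Most Activin feedback genes fell. Lefty1 fell to 1.6 ± 0.2 CPM and Lefty2 to 1.0 ± 0.3 CPM, log2 fold changes of -5.70 ± 0.63 and -5.36 ± 0.73, and Nodal fell to 38.9 ± 4.6 CPM (-0.99 ± 0.10). Of 12 feedback genes 8 fell, among them Smad7 (-1.97 ± 0.20) and Pmepa1 (-1.68 ± 0.10), and 1 rose, Foxh1 (0.24 ± 0.07), a Smad partner named after its value was seen. Adjusted over the list alone 9 fell and 1 rose. The list was called by camera (adjusted p = 2.2e-18), and adjusted p = 0.027 with an estimated correlation.

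Other large falls were those of the nucleic acid sensor Zbp1 (-3.66 ± 0.77) and Mup6 (-3.60 ± 0.59), at 0.07 ± 0.07 and 0.17 ± 0.11 CPM with SB and so imprecise in size. The largest rises were those of Tmem132e (4.43 ± 0.37), the LIM homeobox gene Lmx1b (4.24 ± 0.35), the anterior forebrain gene Hesx1 (3.70 ± 0.22, from 1.7 ± 0.4 to 22.1 ± 1.7 CPM), Epn3 (2.88 ± 0.27) and Coch (2.85 ± 0.33). Vprbp itself was lower with SB by edgeR's quasi-likelihood test (-0.18 ± 0.06, Benjamini-Hochberg adjusted p = 0.049), a call lost in each fit without 1 library, while Foxh1, Spp1 and Cdh2, also named for SB, lost theirs in some.

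Pluripotency genes fell with SB. Of 14 core pluripotency genes 10 fell, among them Pou5f1 (-0.94 ± 0.06, from 700.6 ± 36.1 to 364.2 ± 27.9 CPM), Dppa5a (-1.60 ± 0.09), Dppa2 (-1.33 ± 0.11) and Utf1 (-0.91 ± 0.08), and 1 rose, Lin28a (0.71 ± 0.08), named after its value was seen. The counts were the same adjusted over the list alone. Camera called this list lower (adjusted p = 1.0e-11), and adjusted p = 0.030 with an estimated correlation. Of 19 naive pluripotency genes 6 fell, among them Fgf4 (-1.0 ± 0.09), Tcl1 (-1.11 ± 0.11) and Nanog (-0.49 ± 0.09), and 1 rose, Spp1, also with adjustment over the list alone (camera adjusted p = 0.0012, but adjusted p = 0.24 with an estimated correlation). Of 15 primed epiblast genes 9 fell, among them Dnmt3a (-0.84 ± 0.12), and 2 rose, Sox11 (1.12 ± 0.12) and Cdh2 (0.88 ± 0.24), the latter named after its value was seen. The counts adjusted over the list alone were the same (camera adjusted p = 0.0022, but adjusted p = 0.33 with an estimated correlation).

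Targets of FGF/ERK signalling fell with SB while BMP targets rose. Of 13 FGF/ERK targets 10 fell and 0 rose, among them Etv4 (-0.85 ± 0.10), Spry4 (-0.89 ± 0.11) and Spry1 (-0.65 ± 0.09), or 11 adjusted over the list alone. The list was called lower (camera adjusted p = 1.4e-07), but adjusted p = 0.14 with an estimated correlation. Of 10 BMP targets 6 rose and 0 fell, likewise adjusted over the list alone, with the inhibitors of differentiation Id1 (2.01 ± 0.44), Id2 (1.93 ± 0.24) and Id3 (2.84 ± 0.51) among them. That list was called higher (camera adjusted p = 0.0022), but adjusted p = 0.19 with an estimated correlation.

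Trophoblast genes rose: 9 of 13 did and 0 fell, among them Peg10 (1.31 ± 0.09, from 589.0 ± 60.7 to 1464 ± 146 CPM), Gata2 (2.23 ± 0.24) and Hand1 (2.03 ± 0.31), or 10 adjusted over the list alone. The list was called (camera adjusted p = 4.9e-08), but adjusted p = 0.14 with an estimated correlation. Of 11 neural crest and surface ectoderm genes 7 rose, among them Dlx3 (0.96 ± 0.14), and 2 fell, among them Sox10 (-1.31 ± 0.20), or 8 and 2 adjusted over the list alone (camera adjusted p = 0.023, but adjusted p = 0.16 with an estimated correlation). This list shares Krt8, Krt18 and Gata3 with the trophoblast list and Msx1 and Msx2 with the BMP list, so these lists are not separate evidence. Neuroectoderm genes moved both ways, with 6 of 23 higher, led by Hesx1, and 5 lower, among them Sox1 (-0.88 ± 0.13) and Fgf15 (-3.25 ± 0.34). The counts adjusted over the list alone were the same, and the list was not called (camera adjusted p = 0.65).

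Of 23 p53 targets 9 fell and 0 rose, led by Pmaip1 (-1.27 ± 0.12), or 11 adjusted over the list alone (camera adjusted p = 0.0020, but adjusted p = 0.24 with an estimated correlation). Of 12 Hox genes 5 fell, among them Hoxb1 (-1.49 ± 0.28), or 6 adjusted over the list alone (camera adjusted p = 0.0042, but adjusted p = 0.16 with an estimated correlation). Epcam (-0.64 ± 0.08), Cdh1 (-0.45 ± 0.07) and Grhl2 (-1.06 ± 0.13) fell and the mesenchymal regulator Snai1 (1.25 ± 0.23) rose. Inhbb, which encodes an Activin subunit, fell (-2.37 ± 0.13), and the receptor gene Tgfbr2 rose (1.24 ± 0.19). These are single members of the list of epithelial and mesenchymal genes and of a list of Activin pathway components. Neither list is described as a whole for SB here. Of the 12 fibroblast genes 3 rose and 2 fell, or 4 and 4 adjusted over the list alone (camera adjusted p = 0.96).

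**Figure D3:**
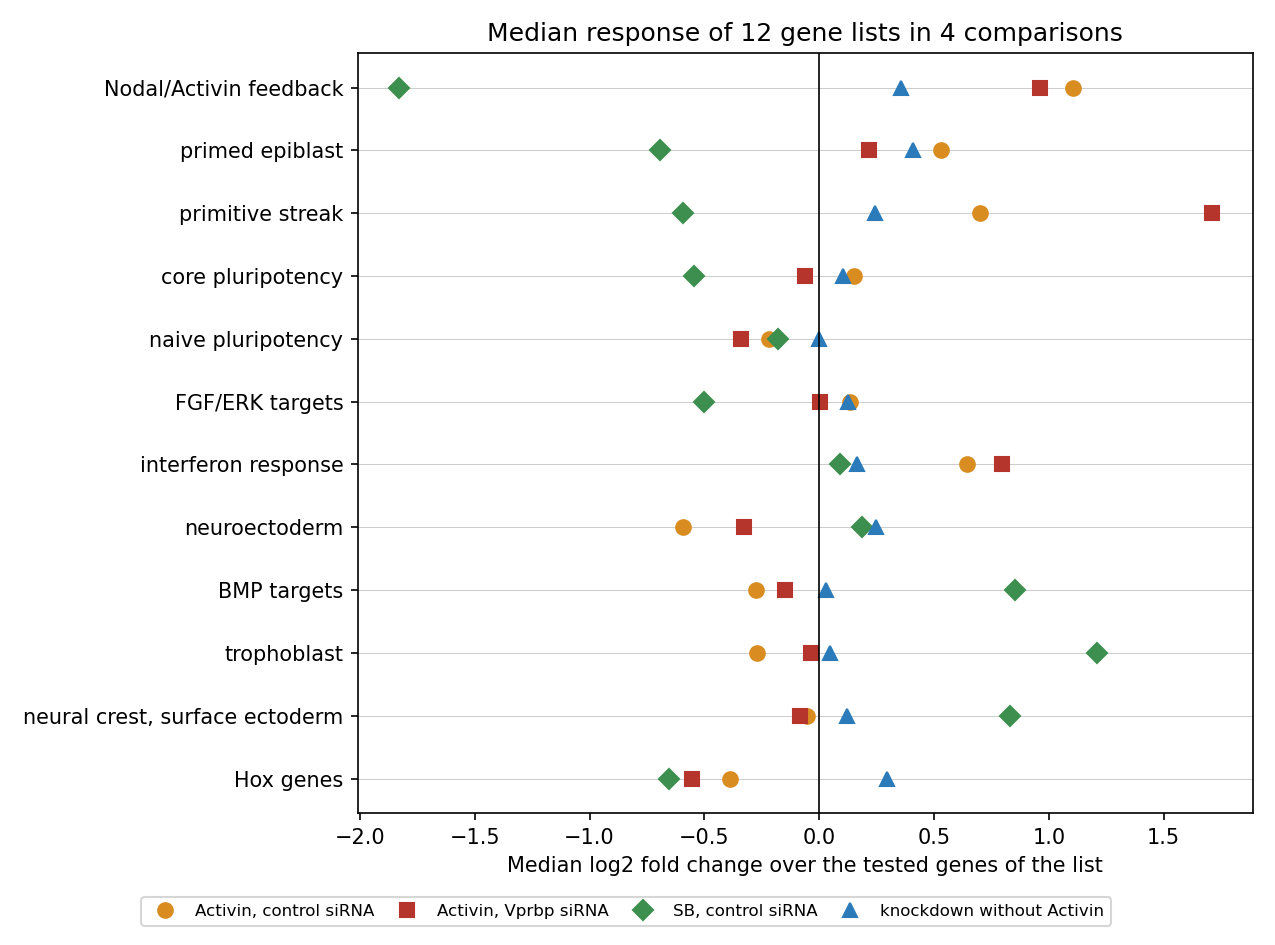
Median log2 fold change (x axis) over the tested genes of 12 gene lists (y axis) in 4 comparisons, with 1 marker per comparison. The feedback list lies at 1.11 with Activin and -1.83 with SB in control siRNA cells, while the BMP and trophoblast lists lie at 0.85 and 1.21 with SB.

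Set directly against SB, Activin differed at 5547 genes, 2780 higher and 2767 lower with Activin. Among the genes highest with Activin were Lefty2 (7.56 ± 0.67), Lefty1 (7.34 ± 0.61), Zbp1 (5.49 ± 0.62) and Trim67 (5.27 ± 0.69), while Nodal differed by 1.57 ± 0.10. The genes highest with SB were Tmem132e (-5.44 ± 0.42), Lmx1b (-4.94 ± 0.39), Zbtb16 (-4.16 ± 0.43), Nfix (-4.07 ± 0.23) and Hesx1 (-3.81 ± 0.23). Of 12 feedback genes 9 were higher with Activin and 0 lower, or 10 and 1 adjusted over the list alone. This list was called by camera (adjusted p = 8.95e-23), and adjusted p = 0.011 with an estimated correlation. Of 13 primitive streak genes 7 were higher, among them T (2.52 ± 0.69), likewise adjusted over the list alone (camera adjusted p = 5.1e-05, but adjusted p = 0.22 with an estimated correlation).

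The responses to Activin and to SB ran in opposite directions for many genes. Of the 431 genes that rose with Activin, 204 fell with SB and 19 rose, where independent lists would share 48.8 and 48.5. Of the 274 that fell with Activin, 115 rose with SB and 20 fell, against 30.8 and 31.0. Over 14600 genes, which are not independent replicates, the fold changes correlated at r = -0.22 with a covariance of -0.0460. Both comparisons use the same 3 untreated libraries, which alone gave r = 0.50 and a covariance of 0.0228 in simulated groups without effects, a difference in covariance of -0.0687. The correlation was -0.10, -0.11 and -0.14 without control siRNA replicate 1, 2 and 3, and -0.14 without the 3 libraries that lay apart. The Activin response of Vprbp siRNA cells, which shares no library with the SB response, gave r = -0.25 against a simulated value of -0.00076. These simulations drew each gene independently and lack shifts of a whole library, so they do not give the range of r by chance.

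For Vprbp knockdown without Activin the number of genes called depended on the pairing of same-numbered libraries and on the libraries fitted. In the fit over all 15 libraries without pairing, by edgeR's quasi-likelihood test 6 of 14600 were called, with 1191 at an unadjusted p under 0.05, and DESeq2 called 31. Besides the fall of Vprbp, 5 genes rose: the interferon-induced transmembrane gene Ifitm3 (0.61 ± 0.08, from 83.0 ± 3.9 to 127.1 ± 6.0 CPM), Zfp608 (0.79 ± 0.13), Meis1 (0.83 ± 0.14), the ephrin receptor gene Epha4 (0.48 ± 0.08) and Pgap1 (0.50 ± 0.09). Lefty1 (0.44 ± 0.39), Lefty2 (0.60 ± 0.42) and Nodal (0.18 ± 0.10) did not pass in that fit.

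In the same fit primed epiblast genes were the group with the smallest list p. None of its 15 genes passed over all genes, but 7 rose and 0 fell when adjusted over the list alone, with Lin28b at 0.27 ± 0.07, Sox11 at 0.41 ± 0.12 and Dnmt3b at 0.38 ± 0.12. The list was called higher (camera adjusted p = 1.7e-10), but adjusted p = 0.26 with an estimated correlation. Of 12 Hox genes 0 passed over all genes and 2 rose adjusted over the list alone, with Hoxa5 at 0.69 ± 0.19 and Hoxb1 at 0.79 ± 0.24 (camera adjusted p = 0.0020, but adjusted p = 0.26 with an estimated correlation). Cholesterol synthesis genes leaned lower, with a median of -0.12, Insig1 at -0.22 ± 0.08 and 0 of 18 called over all genes or adjusted over the list alone (camera adjusted p = 0.0015, but adjusted p = 0.70 with an estimated correlation). Feedback genes had a median of 0.35 with 0 of 12 called either way (camera adjusted p = 0.027, but adjusted p = 0.70 with an estimated correlation), and the call was lost without control siRNA replicate 3 (median 0.08) and without Vprbp siRNA replicate 1 (0.28) or 2 (0.18). Stress response genes had a median of -0.27 with 0 of 17 called either way (camera adjusted p = 0.025, but adjusted p = 0.70 with an estimated correlation), which was 0.11 without control siRNA replicate 3.

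Same-numbered libraries deviated together in this pair of groups, and a replicate block raised the count to 18, with 15 higher and 3 lower, all 6 genes included. A block on these 6 libraries alone, an alternative chosen after seeing the data, called 333 of 14063 genes, 218 higher and 115 lower. In it Lefty1 (0.46 ± 0.07) and Lefty2 (0.66 ± 0.09) rose (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.00049 and 0.00042), though not in the block over all 15 libraries (adjusted p = 0.71 and 0.63), while Nodal (0.19 ± 0.07) did not pass (adjusted p = 0.22 by the same edgeR test). Without a block the same 6 libraries gave Lefty1 0.44 ± 0.57 and Lefty2 0.60 ± 0.60, and neither passed (adjusted p = 0.90 and 0.87 by that edgeR test). Because the pairing was found in these same counts, the p-values of the block on 6 libraries may be too small. Of 12 feedback genes 5 rose in the block on 6 libraries, or 7 adjusted over the list alone, and of 15 primed epiblast genes 9 rose, among them Dnmt3b (0.37 ± 0.07) and Sox11 (0.41 ± 0.08), or 10 adjusted over the list alone. Of 17 stress response genes 6 fell, among them Ddit3 (-0.76 ± 0.13) and Trib3 (-0.69 ± 0.10), named after their values were seen, or 8 adjusted over the list alone. These 3 lists were called with the preset correlation (camera adjusted p = 5.6e-10, 2.7e-23 and 1.2e-09), but adjusted p = 0.54, 0.51 and 0.54 with an estimated correlation. In the same block 1 of 18 cholesterol synthesis genes fell, or 8 adjusted over the list alone. Of 11 Hox genes 2 rose, or 4 adjusted over the list alone, and of 20 neuroectoderm genes 5 rose, or 6 rose and 1 fell adjusted over the list alone. These lists too were called with the preset correlation (camera adjusted p = 2.9e-05, 0.00011 and 0.0011), but each had adjusted p = 0.54 with an estimated correlation.

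Vprbp and Ifitm3 were called in each of the 6 fits without 1 library. With only the 6 libraries fitted and no block the count was 1: Ifitm3 was called (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.035) and the fall of Vprbp, still -0.49 ± 0.07, was not (adjusted p = 0.15 by the same edgeR test). The count of the fit over all libraries was 2 without Vprbp siRNA replicate 1 or control siRNA replicate 2 or 3, 3 without Vprbp siRNA replicate 2 and 37 without Vprbp siRNA replicate 3, and leaving out the 3 libraries that lay apart gave 76.

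For Vprbp knockdown with Activin the number of genes called also depended on the fit, and Ifitm3 rose again. A replicate block called 51 genes and DESeq2 called 76. In the fit over all libraries without a block, edgeR's quasi-likelihood test called 6, with 1532 at an unadjusted p under 0.05. Besides the fall of Vprbp, 5 genes rose, among them Ifitm3 (0.53 ± 0.08, from 101.2 ± 0.6 to 145.9 ± 17.4 CPM), the semaphorin gene Sema4c (0.66 ± 0.10), Ctdsp1 (0.53 ± 0.09) and Spred3 (0.66 ± 0.12), an inhibitor of ERK signalling. Lefty1 (0.16 ± 0.37), Lefty2 (0.18 ± 0.39) and Nodal (-0.04 ± 0.10) did not pass the test.

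In the fit over all libraries 0 of 15 primed epiblast genes passed over all genes and 3 rose adjusted over the list alone, with Dnmt3b at 0.56 ± 0.12 and Sox11 at 0.44 ± 0.12 (camera adjusted p = 1.8e-05, but adjusted p = 0.32 with an estimated correlation). Axial mesendoderm genes had a median of 1.44, with 0 of 11 called over all genes and 1 adjusted over the list alone, Chrd at 0.64 ± 0.20 and Shh at 2.61 ± 0.87 (camera adjusted p = 0.00059, but adjusted p = 0.32 with an estimated correlation). Primitive streak genes had a median of 1.16 with 0 of 13 called either way (camera adjusted p = 0.00090, but adjusted p = 0.32 with an estimated correlation). T and Fgf8 stood at 1.44 ± 0.53 and 1.16 ± 0.38. Both lists rested on Vprbp siRNA with Activin replicate 1, where T was at 71.9 CPM against 19.1 and 15.7 in the other replicates, and without it their medians were both 0.19 and neither was called.

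Of 23 p53 targets 0 were called either way and the median was -0.10 (camera adjusted p = 0.00059, but adjusted p = 0.32 with an estimated correlation). Interferon response genes had a median of 0.27, with 0 of 15 called over all genes and 1 adjusted over the list alone (camera adjusted p = 0.0029, but adjusted p = 0.30 with an estimated correlation). By the edgeR test 0 genes were called when control siRNA with Activin replicate 1, 2 or 3 was left out of the fit over all libraries. Vprbp lost its call too, though its log2 fold change stayed at -0.37, -0.38 and -0.35. The calls of that fit were therefore lost with any 1 of those libraries, while the size of the Vprbp change was not. Without Vprbp siRNA with Activin replicate 2 or 3 the count was 3 or 21, with Vprbp outside the threshold in both. It was 205 without the 3 libraries that lay apart and 68 when only the 6 libraries compared were fitted. In that fit of 6 libraries the primed epiblast genes Dnmt3b (0.56 ± 0.09), Foxd3 (0.64 ± 0.11), Pou3f1 (0.47 ± 0.06), Sall2 (0.49 ± 0.09) and Zic2 (0.31 ± 0.06) rose. Their Benjamini-Hochberg adjusted p-values by edgeR's quasi-likelihood test were 0.018, 0.022, 0.013, 0.042 and 0.038. No other member of that list was called in it. Foxd3, Pou3f1, Sall2 and Zic2 were named after their values were seen.

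Over 14600 genes the knockdown effects with and without Activin correlated at r = 0.33, against -0.0022 in simulated groups without effects, and at 0.19 without the 3 libraries that lay apart. They share no library. The simulations drew each gene independently, so they lack shifts of a whole library that many genes share. The simulated value therefore does not show how far r can stray from 0 by chance. In the fit over all libraries Vprbp fell and Ifitm3 rose in both. Irgm2 (1.08 ± 0.23) and Ddx58 (0.43 ± 0.11) rose without Activin in the block on 6 libraries. With Activin they rose in the fit of only the libraries compared (0.87 ± 0.14 and 0.59 ± 0.10). Both genes were named here after their values were seen. Of 11 interferon response genes 2 rose and 1 fell in that block, and the list was not called (camera adjusted p = 0.51).

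Activin in Vprbp siRNA cells raised most feedback genes, with 894 genes called, 533 higher and 361 lower. Lefty2 (1.78 ± 0.41) and Nodal (0.36 ± 0.10) rose, and Lefty1 went from 111.8 ± 50.1 to 284.2 ± 37.4 CPM without passing (1.35 ± 0.38, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.070). Of 12 feedback genes 8 rose and 0 fell, led by Pmepa1 (0.94 ± 0.09), or 12 adjusted over the list alone (camera adjusted p = 1.0e-16, and adjusted p = 0.023 with an estimated correlation). The largest rises were those of T (2.73 ± 0.58), Trim67 (2.52 ± 0.48), Enpp2 (2.41 ± 0.50), Bmp2 (2.37 ± 0.59) and Rtp4 (2.28 ± 0.42). The largest falls were those of Ptn (-2.72 ± 0.50), Stra8 (-2.15 ± 0.15), the neural progenitor gene Olig3 (-2.15 ± 0.46), Meis1 (-1.97 ± 0.16) and the retinoic acid binding protein gene Crabp1 (-1.93 ± 0.25). Without Vprbp siRNA with Activin replicate 1, T was at 1.72 and Bmp2 at 1.32, below Trim67 at 2.26. Of 23 neuroectoderm genes 6 fell, among them Sox1 (-0.94 ± 0.12) and Pax6 (-1.11 ± 0.14), and 3 rose, or 7 and 3 adjusted over the list alone (camera adjusted p = 0.038, but adjusted p = 0.20 with an estimated correlation). That neuroectoderm list was not called without Vprbp siRNA replicate 1 (camera adjusted p = 0.073).

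Of 13 primitive streak genes 4 rose, among them Fgf8 (2.06 ± 0.41) and Eomes (1.19 ± 0.31), or 10 adjusted over the list alone (camera adjusted p = 5.0e-07, but adjusted p = 0.16 with an estimated correlation). The median of the primitive streak list was 1.71, and 0.70 without Vprbp siRNA with Activin replicate 1, where the list was still called (camera adjusted p = 2.3e-06). Of 15 interferon response genes 5 rose, among them Bst2 (0.73 ± 0.12), or 8 adjusted over the list alone. That list was called higher (camera adjusted p = 5.0e-07), and adjusted p = 0.023 with an estimated correlation. Of 19 naive pluripotency genes 6 fell, among them Zfp42 (-0.58 ± 0.08), or 10 adjusted over the list alone (camera adjusted p = 7.8e-07, but adjusted p = 0.16 with an estimated correlation). Of 12 Hox genes 1 fell, or 6 adjusted over the list alone (camera adjusted p = 5.1e-05, but adjusted p = 0.063 with an estimated correlation). Dnmt3b rose (1.08 ± 0.12) among 3 of 15 primed epiblast genes, or 6 adjusted over the list alone (camera adjusted p = 2.5e-05, but adjusted p = 0.21 with an estimated correlation). Lefty2, Nodal, T, Bmp2, Enpp2, Eomes and Fgf8 lost their calls in at least 1 of the 6 fits without 1 library. The count was 351 without Vprbp siRNA replicate 3 and 373 when only the 6 libraries compared were fitted.

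No single gene differed detectably between the siRNAs in its Activin response. By edgeR's quasi-likelihood test 0 genes were called for the difference of responses, with 517 at an unadjusted p under 0.05, and DESeq2 called 0. The differences were -0.29 ± 0.54 for Lefty1, -0.43 ± 0.57 for Lefty2, -0.22 ± 0.14 for Nodal and 0.11 ± 0.09 for Vprbp. With both siRNAs 258 genes rose and 128 fell with Activin, and 0 were called in opposite directions. Over the 1213 genes called with either siRNA, 97.9% moved the same way and the fold changes of Vprbp siRNA cells followed those of control siRNA cells with a slope of 1.06, inside the 0.93 to 1.07 of simulated responses without a difference. Over all genes, which are not independent replicates, the 2 responses correlated at r = 0.65, below the 0.68 to 0.72 of the same 20 simulations. These drew each gene independently around fitted effects that carry their own noise, so this does not tell a difference of responses from noise. Without Vprbp siRNA replicate 3 the slope was 0.82, and without Vprbp siRNA with Activin replicate 3 it was 1.29. With the preset correlation 7 lists were called for the difference, and 0 with an estimated correlation.

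**Figure D4:**
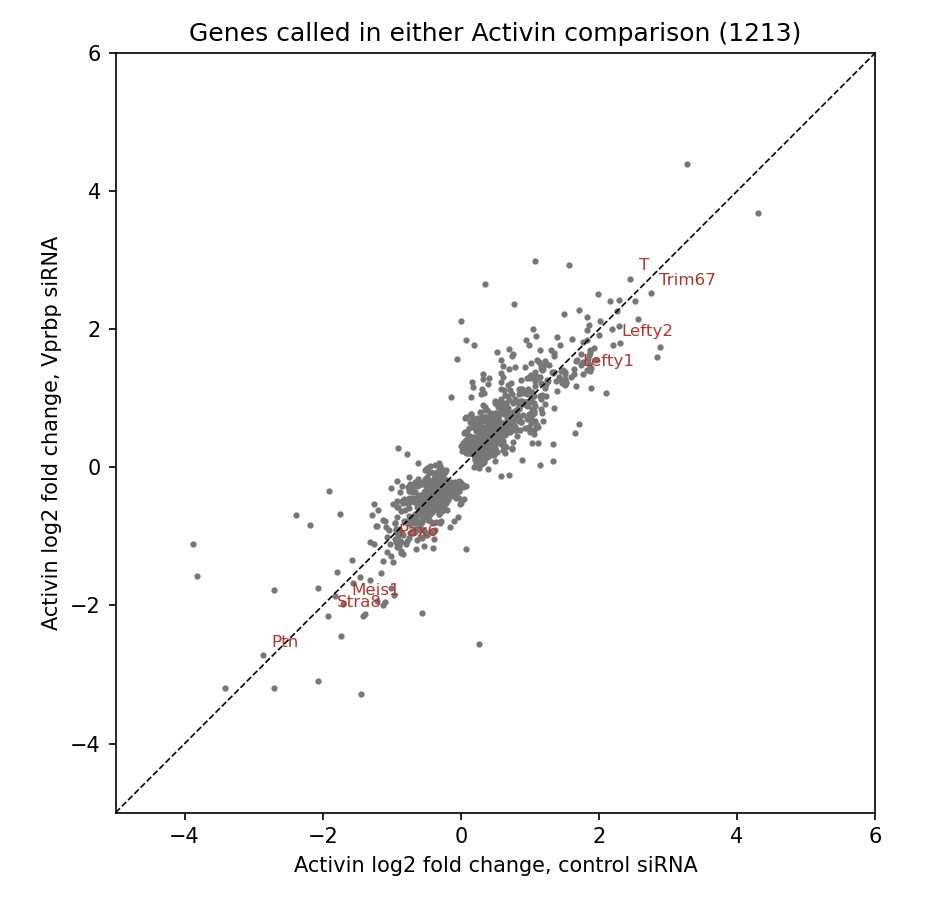
Log2 fold change with Activin in control siRNA cells (x axis) against Vprbp siRNA cells (y axis), 1 point for each of the 1213 genes called in either, with the dashed line of equality. The named genes lie near the line, such as Trim67 at 2.75 and 2.52.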

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

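The tests of why the untreated replicate 3 libraries lay apart, and the test of fibroblast genes, were chosen after the results they measure were seen.

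By a test of the difference itself, the Activin response differed between siRNAs for 7 lists at the preset correlation. Camera adjusted p-values were 0.000198 for germ cell genes, 0.0120 for mesoderm genes, 0.0124 for naive pluripotency, definitive endoderm, core pluripotency and cell cycle genes, and 0.0309 for FGF/ERK targets. The definitive endoderm median was 0.45, but -0.06 without Vprbp siRNA with Activin replicate 1. With an estimated correlation 0 of them were called, and the smallest adjusted p was 0.0602, for germ cell genes. The edgeR quasi-likelihood test called 0 genes for this difference (517 at an unadjusted p under 0.05, DESeq2 0). Of the 40 splits that exchange siRNA labels within each Activin level 40 gave as many, which a count of 0 fixes in advance, so they say nothing about chance. The highest other split gave 139 genes. Such exchanges can carry the knockdown effect itself, which averaged over Activin levels called 137 genes, into the difference, and this was not tested.

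In reads outside the main measurement, the share of fragments outside genes was 16.0% in Vprbp siRNA with Activin replicate 3, above the untreated control siRNA libraries, of which the highest had 13.6%. That library also had the most of the nuclear RNA Malat1, at 1287 CPM.

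Replicate 3 of both untreated groups lay toward the SB group. The 13.5 M (mega) gene counts of the control siRNA library lay inside the 13.1 M to 15.5 M of the other untreated libraries. This argues against low depth for that library. The 15.5 M is the other library apart, replicate 3 of Vprbp siRNA, the highest of all libraries, and depth was not tested for it. The control siRNA library had 11.8% of fragments outside genes, below the 12.4% to 13.6% of the other untreated libraries. The 12.4% is again replicate 3 of Vprbp siRNA, below the 12.6% to 13.6% of replicates 1 and 2, so RNA quality stays open. The deviation of the control siRNA library from replicates 1 and 2 correlated over genes at -0.262 with the difference of Activin from SB. That of the Vprbp siRNA library did so at -0.301, and the feedback genes lay lower in both, by medians of -0.62 and -0.38. Both libraries were singled out for lying toward SB on component 1, which runs from Activin to SB. These values therefore largely restate that choice. Lower Activin pathway activity in these cultures may be a source, but these values cannot test it. That explanation stays open beside RNA quality.

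Interferon response genes rose with Activin, with a median of 0.72 averaged over both siRNAs and 9 of 15 genes higher, or 10 adjusted over the list alone (camera adjusted p = 1.1e-06, and adjusted p = 0.029 with an estimated correlation). With 1 library left out the lowest median was 0.63, without Vprbp siRNA replicate 3, and the list stayed called at the preset correlation in all 12 fits, which argues against a single library, though with an estimated correlation the call was lost in 5 fits, without control siRNA replicate 1 (adjusted p = 0.0538), 2 (0.0643) or 3 (0.0527), Vprbp siRNA replicate 1 (0.0536) and control siRNA with Activin replicate 1 (0.0520). The fibroblast list had a median of -0.23, which argues against feeder cells. With the share of fragments outside genes as a covariate the median was 0.73, which argues against that share as the cause. A response to Activin may be the source, as a hypothesis found and tested on the same data. SB did not reverse the rise of every member, as Ddx58 rose with SB too (1.39, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 7.3e-06). Values of the other members with SB are not given here.

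For the other comparisons 3 against 3 libraries make 10 splits, too few for a share under 0.05. The real split called 705 genes for Activin, 3294 for SB, 5547 for Activin against SB, 6 for knockdown without Activin and 6 with it, and the highest other split called 0 by edgeR in each. For Activin with Vprbp siRNA the real split called 894 and the highest other split 5. The real split was the 1 of 10 with as many genes each time. Every other split mixes the groups compared, so a real difference adds to the spread and lowers its count. The low counts of the other splits therefore do not measure chance.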

How the results depend on the processing

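The alternatives that leave out the 3 libraries that lay apart, use the share of fragments outside genes as a covariate, or fit 6 libraries with a replicate block were chosen after seeing the data. Of the values of main results under alternatives, 170 kept their direction and size or side of the threshold, 39 became weaker, 19 stronger, 32 moved and 0 reversed. For the rest the cause was not tested unless stated.

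Tested against a fold of 1.5, a stricter null by construction, the counts were 19 for Activin, 446 for SB and 1138 for Activin against SB. They were 38 for Activin with Vprbp siRNA, and 0 by edgeR's glmTreat for knockdown without and with Activin. Against no change, edgeR's quasi-likelihood test gave these 2 knockdown comparisons 1191 and 1532 genes at an unadjusted p under 0.05, and DESeq2 called 31 and 76. With a replicate block the counts were 1058 for Activin, 18 and 51 for knockdown without and with Activin, and the slope of the knockdown effects was 1.14 against 0.93. That slope is taken over genes called in either knockdown comparison, only 10 genes for 0.93 (r = 0.54). Each setting uses its own genes, so slopes under different settings cover different sets. With no low-count filter knockdown gave 10 and 15. With only the libraries compared it gave 1 and 68, the call of Vprbp being lost without Activin, and Activin with Vprbp siRNA gave 373. The 6 libraries with a replicate block gave 333 for knockdown without Activin, and the covariate 55 for knockdown with Activin. In the fits over all libraries with a block, RLE factors, library totals, either filter or the covariate the 6 and 6 main calls were kept.

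Without the 3 libraries knockdown gave 76 and 205 genes, the difference of responses 1, the slope of knockdown effects 1.13, the correlation of the SB and Activin responses -0.14 against -0.22, and the lists called for knockdown with Activin and for the difference 9 and 3. With a filter of 1 CPM that correlation was -0.27. With an estimated correlation the lists called were 1 for Activin, 2 for SB, 1 for Activin against SB, 0 for knockdown without and with Activin, 2 for Activin with Vprbp siRNA and 0 for the difference, by camera. Fry called 6 lists for Activin, 15 for SB, 19 for Activin against SB and 10 for Activin with Vprbp siRNA. It called 0 for knockdown without and with Activin and 0 for the difference.

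Leaving out 1 library each, counts ranged from 265 to 721 for Activin, 2399 to 3424 for SB, 4533 to 4774 for Activin against SB, 2 to 37 and 0 to 21 for knockdown without and with Activin, 351 to 1167 for Activin with Vprbp siRNA and 0 to 0 for the difference. Vprbp ranged from -0.54 to -0.44 without and -0.42 to -0.33 with Activin. The slope of the Activin responses ranged from 0.82 to 1.29, that of the knockdown effects from 0.48 to 2.78 and the correlation of SB and Activin from -0.21 to -0.10. Lists called ranged from 12 to 15 for Activin, 13 to 15 for SB, 12 to 13 for Activin against SB, 4 to 8 and 6 to 18 for knockdown without and with Activin, 11 to 15 for Activin with Vprbp siRNA and 5 to 13 for the difference.

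Signs turned for 7 values, none of them a main result. Without the 3 libraries Lefty2 and Nodal for knockdown with Activin were -0.029 and 0.018, Cyp26a1 for the averaged Activin response -0.35 and the definitive endoderm median for the difference -0.043. With 1 library left out Lefty2 ranged from -0.027 (without Vprbp siRNA with Activin replicate 1) to 0.29 and Nodal from -0.077 to 0.020 (without the same library; 0.0033 without control siRNA with Activin replicate 3). Cyp26a1 ranged from -0.31 to 0.53 and the definitive endoderm median from -0.061 to 0.64, both negative without that library alone. For the difference, Lefty1 ranged from -0.61 to 0.058 and was positive without Vprbp siRNA replicate 2 (0.018) or control siRNA replicate 3, and the feedback median ranged from -0.26 to 0.11 and was positive without Vprbp siRNA replicate 1 (0.030) or 2 (0.031) or control siRNA replicate 3. The stress median for knockdown without Activin ranged from -0.40 to 0.11, positive without control siRNA replicate 3 alone.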

Other observations

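The average contrasts, the test of the knockdown effect against the SB response and the test of retinoic acid genes were chosen, or had their bounds changed, after results they measure were seen.

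Of 13 germ cell genes 5 fell with SB, among them Mael (-1.23 ± 0.14), Dazl (-0.85 ± 0.14) and Ddx4 (-0.50 ± 0.10), and Kit (0.39 ± 0.08) rose, with the same counts adjusted over the list alone (camera adjusted p = 0.0069, but adjusted p = 0.14 with an estimated correlation). Of 5 genes of the 2-cell-like state 4 fell with SB, also adjusted over the list alone, with a median of -1.90 (camera adjusted p = 0.013, but adjusted p = 0.24 with an estimated correlation). Of 14 Wnt targets 4 fell with SB, among them Cdx1 (-1.99 ± 0.36) and Axin2 (-0.39 ± 0.13), or 6 adjusted over the list alone (camera adjusted p = 0.044, but adjusted p = 0.29 with an estimated correlation). The Wnt list was not called without control siRNA replicate 2 (adjusted p = 0.054) or control siRNA with SB replicate 3 (adjusted p = 0.062). Axin2 was named after its value was seen.

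Averaged over both Activin levels, 137 genes were called between Vprbp siRNA and control siRNA, 97 higher and 40 lower. Of 15 primed epiblast genes 4 rose, Dnmt3b (0.47 ± 0.08), Sox11 (0.43 ± 0.09), Lin28b (0.20 ± 0.05) and Cdh2 (0.80 ± 0.17), or 10 adjusted over the list alone (camera adjusted p = 3.2e-11, but adjusted p = 0.32 with an estimated correlation). The largest rises were those of Gbp4 (1.25 ± 0.28), Pde4b (1.07 ± 0.25) and Nrcam (0.95 ± 0.19), and Stra8 was among the genes that fell (-0.75 ± 0.10). The count was 24 without control siRNA with Activin replicate 1 and 395 without Vprbp siRNA replicate 3, and Cdh2, Lin28b, Sox11 and Dnmt3b each lost their calls in at least 3 of the 12 fits without 1 library. It was 475 when the 3 libraries that lay apart were left out.

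The averaged knockdown effect followed the averaged Activin effect, with r = 0.341 over genes, which are not independent replicates. Simulated groups without effects gave -0.00668, but these drew each gene independently and so lack shifts of a whole library. Of the genes called for both, 59 rose with both and 15 fell with both, where independent lists would share 8.19 and 2.96. Another 6 rose with knockdown and fell with Activin, against 7.18, and 0 did the reverse, against 3.38. Without the 3 libraries that lay apart r was 0.240, and with the share of fragments outside genes as a covariate 0.317; unequal spread within groups by itself gave 14.6% of the covariance, and less that part r on log2 CPM was 0.305 over all libraries and 0.214 and 0.325 in these 2 settings, which argues against the libraries, the covariate or the spread as the whole cause. With the effects estimated from different libraries r ranged from 0.0418 to 0.374 over 6 splits, so a part from shared libraries cannot be told apart from an effect. Higher pathway activity after knockdown may be a source, but the knockdown effect with Activin correlated with the SB response, with which it shares no library, at r = 0.0473, and at -0.104 without the 3 libraries, so its sign depends on them and the question stays open. The bound for that test first named the value over all libraries alone, which would have argued against this explanation, and was extended to both values after the first was seen.

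Activin may lower the retinoic acid response, a hypothesis formed after Stra8, Meis1 and Crabp1 were seen to fall. A list of 18 other genes related to retinoic acid was written for it and first tested whole, with a median of -0.38 over both siRNAs. Because 5 of them stand in lists whose results were already known, the test was repeated on the other 13, of which 6 fell, among them Crabp2 (-1.62 ± 0.22), Cyp26b1 (-0.92 ± 0.23) and Rarb (-0.44 ± 0.12), and 1 rose, Dhrs3 (0.68 ± 0.14). Their median was -0.32 (camera p = 0.00020, and p = 0.028 with an estimated correlation, unadjusted). With SB the 13 genes had a median of 0.25, with 4 higher and 3 lower, and the 18 genes a median of -0.024, with 4 higher and 6 lower. The SB response moved neither list to a call (limma camera, unadjusted p = 0.62 and 0.40). The retinoic acid degrading enzyme gene Cyp26a1 did not pass with Activin (0.31 ± 0.42, but -0.31 without Vprbp siRNA with Activin replicate 1), so the hypothesis stays open.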
